A study of Mus musculus with 8 samples.

How the data were processed

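Gene expression was measured by polyA RNA sequencing of stranded mRNA libraries from 8 samples in 4 groups of 2, per the labels' protocols. The deposited table holds whole-number read counts per gene symbol, which the authors did not normalise, as the values show. FastQC, STAR 2.5.3a, featureCounts and the builds mm10 and GRCm38 are named, with no role or order, in the submitters' processing notes. The annotation and the strand setting of the counting are not given in the sources used here, so reads of genes that overlap on opposite strands, may not be separable. Of the genes that the naming rule below takes and the text names, these are Yap1, Erbb2, Avil, Bcas1, Car9, Ccna2, Ccnd1, Ddn, E2f8, Gpi1, Gpr17, Kcnt2, Miat, Nefl, Nrip2, Nrn1, Olig1, Ostn, Padi2, Plin4, S1pr3, Slc2a1, Tagln, Tgfb2 and Tk1. Lats2, Nrip2 and Gbp4 overlap another gene on the same strand. Each of the 13607 symbols reached 1 CPM in at least 2 libraries, so genes below that level were not analysed here, and low transcripts cannot be judged absent. The table held 0 mitochondrially encoded transcripts, so the list of these fixed beforehand was not analysed here.

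Each count column was matched to its sample by its title, and groups came from the labels. Replicates were compared first: chi-square per degree of freedom between the 2 libraries of a group was 12.7 in controls, 5.61 in HER2CA day 15, 4.05 in the libraries labelled 4OH-TAM and 733 in gliomaspheres (21.8 without Rn45s and Lars2), so no pair agreed within sampling noise and each library was counted as 1 replicate. Depth was 15517708 to 28231426 counts per library.

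Counts were analysed in R 4.3.3 with edgeR 4.0.16. TMM factors were used, filterByExpr kept all 13607 genes, and a quasi-likelihood model with 1 mean per group was fitted to all 8 libraries, leaving 4 residual degrees of freedom (common biological coefficient of variation 0.0685). The 5 comparisons were tested with glmQLFTest and Benjamini-Hochberg adjustment over all genes, at a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM with TMM-scaled library sizes. A fold against a group at 0 counts was computed against 3 counts over the group and is a lower bound; with 1 to 3 counts, the counts of both groups are given, summed over 2 libraries, and any 95% interval covers counting error only. Gene lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a comparison; camera compares the list with other genes, and fry, an alternative, does not.

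The 22 tested lists covered YAP/TAZ targets, ERK outputs, DNA replication, mitosis, astrocyte, neural stem, oligodendrocyte, neuronal, microglia, fibroblast and mural, endothelial, ependymal, reactive astrocyte, matrix, actin and adhesion, cholesterol, glycolysis, hypoxia, ATF4, p53, interferon and inflammatory transcripts. The lists, tests and most alternatives were fixed before the data were examined. So was the rule for named genes, which takes Yap1, Wwtr1 and Erbb2 everywhere. In the first 4 comparisons it adds the 6 largest increases and 6 largest decreases among genes past the threshold, with all libraries of one group above the other and at least 5 CPM in the higher group. It also adds the 2 members with the lowest p, in the list's direction, of each of up to 8 called lists. It takes 3 genes in each direction in the fifth comparison, and allows every YAP/TAZ target past the threshold in the comparison of the 2 day 15 groups. Not every gene the rule takes is named in the text. Names outside it are Gpc5 and Fgf21, which are at 0 counts in a group, and Rn45s, Lars2, Wars, Gars, Ctss, Tyrobp, Cx3cr1, Cd68, P2ry12, Tmem119, Csf1r and Ly86, chosen after their values were seen. Ribosomal RNA and clone-named gene models were passed over. Gene positions come from GENCODE M21 on GRCm38, in which 96.6% of the symbols were found; Ctgf, Cyr61 and Nov were not matched by symbol.

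Overlaps between comparisons that share libraries were set beside 20 simulations of unchanged groups. Alternatives were relative log expression and upper-quartile factors, 2 other filters, DESeq2 1.42.0, a test against a 1.5-fold change, a fit with only the 2 groups compared, the replicate letter as a block, each library left out in turn, other set sizes, fry, and camera with an estimated correlation. Camera with an estimated correlation also tests on the 4 residual degrees of freedom of the fit, far fewer than with the preset. A call lost there need not reflect correlation alone. The removal of Rn45s and Lars2 and the use of no scaling factors were chosen after seeing the data.

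The model was tested on simulated data with known answers, drawn for the 13607 genes, with 50 genes changed at each fold size. For the libraries labelled 4OH-TAM against HER2CA day 15 it recovered 22% of 1.25-fold, 80% of 1.5-fold, 96% of 2-fold and 100% of 4-fold changes. False calls made up 3.87% of calls in that simulation, 5.16% for HER2CA day 15 against controls, 3.95% for gliomaspheres against HER2CA day 15, 11.6% for the libraries labelled 4OH-TAM against controls and 14% for gliomaspheres against controls, the last 2 more than 2 times the nominal level. Each rate comes from a single simulated data set, with 20 and 24 false calls in the last 2. In the measured data 59.2% and 64.5% of all genes were called in these 2 comparisons, a far larger share than was changed in the simulation. The simulated rates therefore do not give the share of false calls among the measured ones.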

Results

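RNA was sequenced from cultured mouse astrocytes carrying floxed Yap1 and Taz (Wwtr1) alleles, which Cre recombinase can delete. Per the labels, the cells received lentiviral constructs for a doxycycline-inducible, constitutively active form of the receptor tyrosine kinase HER2 (HER2CA), for the doxycycline-controlled activator rtTA and for CreERT2, a Cre that 4-hydroxytamoxifen (4OH-TAM) switches on. The 8 libraries fell into 4 groups of 2: untransformed control astrocytes kept without doxycycline, HER2CA astrocytes at day 15 with doxycycline and no 4OH-TAM, HER2CA astrocytes at day 15 with doxycycline and 1 µM 4OH-TAM, and gliomaspheres grown in suspension with doxycycline and collected 3 weeks after the start. Total counts ranged from 15517708 in gliomaspheres B to 28231426 in HER2CA day 15 B. The labels list DMSO as a condition for HER2CA day 15 and for gliomaspheres, while the treatment protocol calls HER2CA astrocytes without 4OH-TAM untreated, so whether vehicle was given is not settled. Whether the controls also received the constructs is not given in the sources used here. The labels do not say whether replicates A and B came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. In gliomaspheres B, the ribosomal RNA transcript Rn45s took 5599427 of these counts (36.1%, exact 95% binomial interval 36.06% to 36.11%), against 0.984% to 2.92% in the other 7 libraries. Intervals and bounds on counts cover counting error only.

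The targeted genes were examined first. Yap1 (chromosome 9, 7931999 to 8004596, GRCm38) was at 107 and 103 CPM in the libraries labelled 4OH-TAM and at 101 and 103 CPM in those labelled HER2CA day 15, a log2 fold change of 0.04 (SE 0.0682, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.569). With upper-quartile factors it was 0.25 (adjusted p = 0.00352, edgeR quasi-likelihood). Wwtr1, which encodes TAZ (chromosome 3, 57455649 to 57575910), was at 123 and 122 CPM in the libraries labelled 4OH-TAM against 194 and 210.3 CPM, a log2 fold change of −0.73 (SE 0.0687, edgeR quasi-likelihood adjusted p = 1.25e-07; −0.61 and 0.0738 with no scaling factors). Controls held 144 and 136 CPM of Yap1 and 177 and 168 CPM of Wwtr1. Compared with HER2CA day 15, the Yap1 counts therefore showed no decrease under the knockout label, while Wwtr1 was partly lower. Compared with controls (mean 140 CPM), Yap1 was lower in both day 15 groups. Its mean was 102 CPM in HER2CA day 15 and 105 CPM in the libraries labelled 4OH-TAM. These 2 calls, given below, were lost with no scaling factors. Which exons are floxed is not given in the sources used here, and counts over a whole gene include exons that Cre leaves in place. For this reason the groups are called by their labels, and every direction drawn from them rests on those labels. Mouse Erbb2 (chromosome 11, 98412470 to 98437716) was at 30.5 ± 0.598 CPM (SD, n = 2) in HER2CA day 15 and 32.8 and 31.2 CPM in controls, with an adjusted p of 0.461 (edgeR quasi-likelihood), or 0.0256 with upper-quartile factors. The species and sequence of the HER2CA construct are not given in the sources used here, so these counts need not include it.

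**Figure D1:**
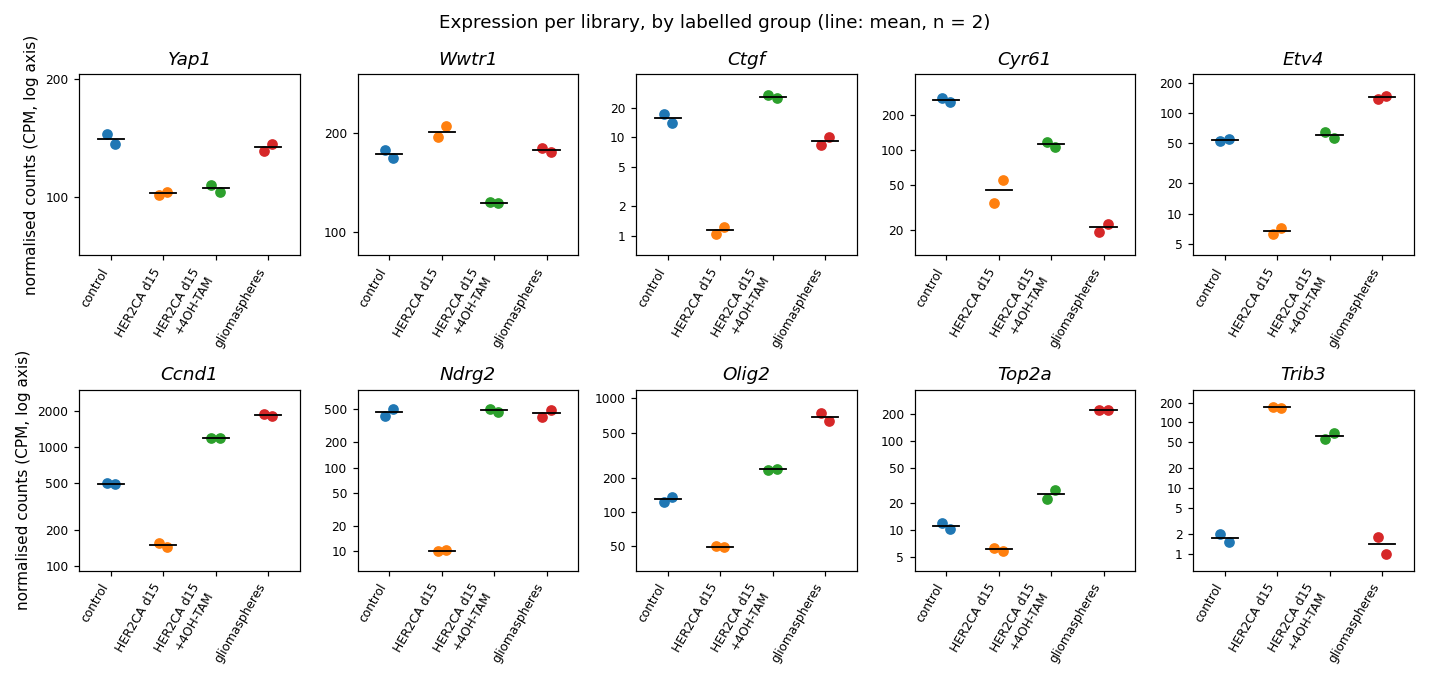
Normalised counts (CPM, log axis) of 10 genes in each of the 8 libraries, by labelled group; each point is 1 library and each line the mean of 2. Yap1 was at 101 to 107 CPM in both day 15 groups, while Ctgf was at 1.05 and 1.24 CPM in HER2CA day 15 and at 26.7 and 25.2 CPM in the libraries labelled 4OH-TAM.

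The series describes 4OH-TAM treatment as a way to remove YAP and TAZ, 2 transcriptional co-activators, during transformation by the oncogene. In the libraries labelled 4OH-TAM, compared with those labelled HER2CA day 15, transcripts of astrocytes, of the oligodendrocyte lineage, of the interferon response and of the ERK pathway were higher. All 4 list calls were lost with an estimated correlation (camera adjusted p = 0.111 for the astrocyte list and 0.106 for the others). Of 26 measured astrocyte transcripts 25 were higher and 0 lower; Ndrg2 had a log2 fold change of 5.55 (SE 0.131) and the water channel gene Aqp4 one of 3.62 (SE 0.0927). Of 18 oligodendrocyte-lineage transcripts 17 were higher and 1 lower, led by the receptor Gpr17 (0.155 ± 0.0247 to 42.4 ± 4.02 CPM, SD, n = 2 in each group) and by Bcas1 (log2 fold change 7.29, SE 0.204). Of 25 interferon-response transcripts 22 were higher and 1 lower, among them Ifit3 (log2 fold change 3.48, SE 0.0966) and Oasl2 (3.82, SE 0.159). Of 19 transcripts induced by ERK signalling 16 were higher and 2 lower, among them the transcription factor Etv4 (log2 fold change 3.13, SE 0.105) and cyclin D1, Ccnd1 (2.98, SE 0.0793).

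Among 21 measured YAP/TAZ targets, 13 were higher and 3 lower in the libraries labelled 4OH-TAM. Ctgf, a matricellular protein gene commonly used as a readout of YAP activity, had a log2 fold change of 4.48 (SE 0.174, edgeR quasi-likelihood adjusted p = 7.62e-12), and Cyr61 one of 1.31 (SE 0.143, adjusted p = 6.32e-07 by edgeR quasi-likelihood). Gadd45b, Nt5e, F3, Axl, Fjx1, Arhgef17, Nuak2, Asap1, Amotl1, Tgfb2 and Rbms3 were also higher, with log2 fold changes from 0.32 to 2.54. The 3 lower targets were Myof (−1.21, SE 0.0745), Ajuba (−0.97, SE 0.124) and the kinase gene Lats2 (−0.47, SE 0.0873). The Rbms3 call was lost without 4OH-TAM replicate B (edgeR quasi-likelihood adjusted p = 0.053), and those of Lats2 (0.327), Rbms3 (0.222) and Tgfb2 (0.0582) with no scaling factors. The list's median was 0.69 with a camera adjusted p of 0.0411, and adjusted p = 0.364 with an estimated correlation. The list's call was also lost without HER2CA day 15 replicate A (median 0.68), without 4OH-TAM replicate B (0.71) and with no scaling factors (0.81, camera adjusted p = 0.102).

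Transcripts of other cell types moved in the same comparison, although these list calls too were lost with an estimated correlation (camera adjusted p from 0.106 to 0.496). Of 20 microglia and macrophage transcripts 19 were higher and 1 lower, including lysozyme Lyz2 (40.4 ± 1.18 to 721 ± 10.8 CPM) and the complement gene C1qb (9.62 ± 0.251 to 64.5 ± 3.3 CPM). Higher members numbered 12 of 14 fibroblast and mural transcripts, such as Anpep (log2 fold change 3.22, SE 0.135) and Vtn (2.97, SE 0.132), 3 of 5 endothelial, 14 of 15 ependymal and 13 of 18 neuronal transcripts. The full lists held 22 fibroblast and mural, 18 endothelial, 20 ependymal and 23 neuronal genes, and the others were not measured. A gene reaching 1 CPM in the 2 libraries of a single group could be measured, so the counts favour members high in some group. Neural stem and progenitor transcripts were higher in 19 of 23 cases, among them Fabp7 (3.12, SE 0.113). Reactive astrocyte transcripts were higher in 21 of 25 cases, among them S1pr3 (4.08, SE 0.1) and Ggta1 (1.97, SE 0.0749), and inflammatory cytokine and NF-kB transcripts in 16 of 19. Mitotic transcripts were higher in 26 of 28 cases, extracellular matrix in 21 of 30 and glycolytic in 13 of 16, while 19 of 24 ATF4 stress response transcripts were lower. Camera adjusted p was 3.85e-17 for the astrocyte list and 1.29e-10 for the oligodendrocyte list. It was 1.43e-09 for microglia, 1.51e-07 for interferon and 3.15e-07 for ERK transcripts. The same test gave 1.63e-06 for reactive astrocyte, 3.31e-05 for neural stem, 4.05e-05 for fibroblast, 0.000152 for matrix and 0.000452 for ATF4 transcripts. It gave 0.00125 for mitosis, 0.0014 for ependymal, 0.00238 for neuronal, 0.00728 for inflammatory, 0.0223 for glycolytic and 0.0326 for endothelial transcripts. None of the 17 list calls held with an estimated correlation. That estimate was −0.00294 for neuronal, 0.00809 for reactive astrocyte and −0.105 for endothelial transcripts, under the preset of 0.01. A larger correlation is therefore not the reason why these lists lost their calls. With an estimated correlation camera also tests on the 4 residual degrees of freedom of the fit, far fewer than with the preset. For the other called lists the estimate was above the preset, so the 2 differences were not separated. Camera gave adjusted p = 0.106 with an estimated correlation for the ERK, oligodendrocyte, neural stem, neuronal, interferon and reactive astrocyte lists. The astrocyte list had adjusted p = 0.111 with an estimated correlation, microglia and ependymal 0.118, fibroblast 0.135 and endothelial and inflammatory 0.151. The values were matrix 0.243, mitosis and ATF4 0.395 and glycolysis 0.496. DNA replication (9 higher, 12 lower of 26, camera adjusted p = 0.498), actin and adhesion (12 and 10 of 29, 0.868), cholesterol synthesis (7 and 13 of 23, 0.377), hypoxia (12 and 4 of 19, 0.154) and p53 targets (6 and 12 of 22, 0.168) did not pass. The glycolysis call was lost with no scaling factors (camera adjusted p = 0.088). With Gpc5, at 0 counts in HER2CA day 15, at its bound, the astrocyte median was 2.77 rather than 2.84. Adjusted over the list alone, the counts differed for neuronal transcripts (13 higher, 4 lower) and glycolysis (14 higher, 2 lower).

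Over all 13607 genes, 10947 differed between the 2 day 15 groups (edgeR quasi-likelihood, adjusted p under 0.05), 5547 higher and 5400 lower in the libraries labelled 4OH-TAM. Of these, 3252 were at least 2-fold higher and 1266 at least 2-fold lower. Upper-quartile factors moved the median log2 fold change of all genes from 0.01 to 0.22 and the split to 6569 higher and 4109 lower. With no scaling factors, chosen after seeing the data, the median was 0.13 and the split 4338 higher and 2037 lower. With a filter of 5 CPM in 2 libraries 4738 were higher and 4770 lower, so the direction of the majority was not stable. The largest increases, by the rule fixed beforehand, were Omg (288 counts against 0, at least 93.3-fold), the long non-coding RNA Miat (1164 against 3 counts, ratio 377, 95% interval 129 to 1832), the sodium channel gene Scn7a (377 against 1 count, ratio 367, 65.4 to 14517), Gpr17, Lpo (311 against 1 count, ratio 302, 53.9 to 11982) and the proteoglycan gene Fmod (log2 fold change 7.78, SE 0.197). The largest decreases were Ostn (−7.27, SE 0.303), Cyp4b1 (−6.71, SE 0.218), Avil (−5.08, SE 0.166), the transcription factor Sp8 (84.6 ± 5.43 to 2.64 ± 0.323 CPM), Bmp3 (−4.14, SE 0.148) and Cdsn (−4.09, SE 0.139).

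**Figure D2:**
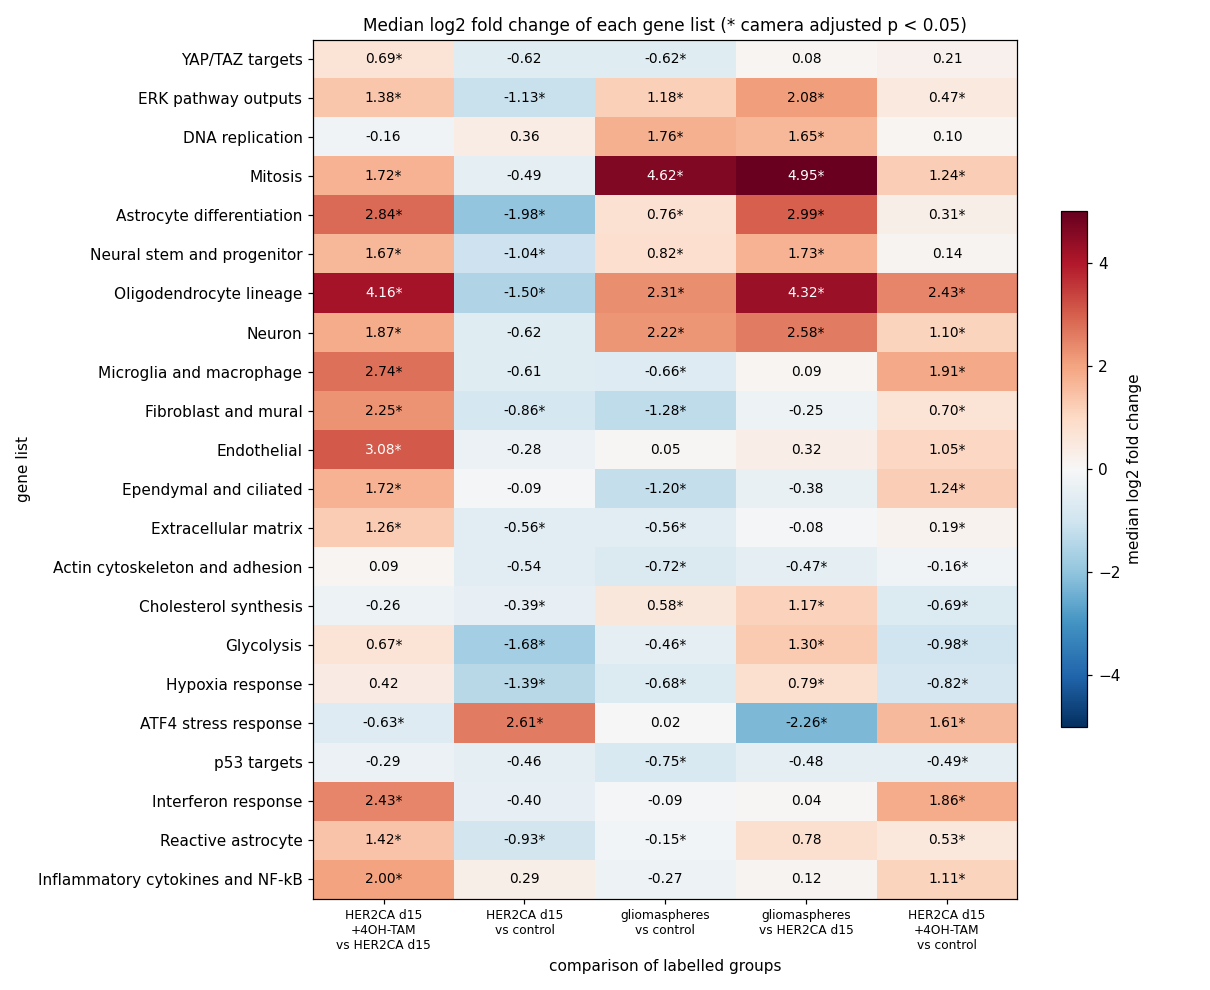
Median log2 fold change of 22 gene lists (rows) in 5 comparisons of labelled groups (columns); colour and number give the median and an asterisk a camera adjusted p under 0.05. The mitosis median was 4.62 in gliomaspheres versus controls and 4.95 versus HER2CA day 15, while the ATF4 stress response median was 2.61 in HER2CA day 15 versus controls.

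The second comparison set HER2CA day 15 against untransformed controls. Of 24 ATF4 stress response transcripts 23 were higher and 0 lower, among them the pseudokinase Trib3 (1.78 ± 0.361 to 169 ± 6.62 CPM) and Nupr1 (31.2 ± 0.7 to 597 ± 18.3 CPM; SD, n = 2 in each group). Of 16 glycolytic transcripts 15 were lower, among them the transporter Slc2a1 (285 ± 5.78 to 32.4 ± 3.83 CPM) and Gpi1 (log2 fold change −2.82, SE 0.108). Of 19 hypoxia-response transcripts 18 were lower and 1 higher, among them carbonic anhydrase Car9 (−3.44, SE 0.132) and Nrn1 (−3.08, SE 0.105). Astrocyte transcripts were lower in 24 of 26 cases, among them Ndrg2 (−5.48, SE 0.131) and Sparcl1 (−2.82, SE 0.0951), and ERK outputs in 15 of 19, among them Etv4 (−2.98, SE 0.105) and Ccnd1 (493 ± 8.09 to 151 ± 7.72 CPM). All 5 list calls were lost with an estimated correlation (camera adjusted p = 0.274 for hypoxia and 0.221 for the others).

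Neural stem and progenitor transcripts were lower in 16 of 23 cases, among them Hes6 (−3.48, SE 0.135), oligodendrocyte-lineage transcripts in 13 of 18, among them Cspg4 (−2.65, SE 0.0768) and Olig1 (−2.30, SE 0.119), and reactive astrocyte transcripts in 13 of 25, among them S1pr3 (−4.15, SE 0.1) and Cd109 (−2.27, SE 0.0833). Extracellular matrix (21 of 30), cholesterol synthesis (15 of 23) and fibroblast and mural transcripts (9 of 14) were lower too. Camera adjusted p was 1.95e-29 for ATF4, 2.54e-13 for astrocyte, 6.28e-10 for glycolysis, 1.76e-08 for hypoxia, 0.000122 for neural stem, and 0.000475 for ERK transcripts. It was 0.00335 for oligodendrocyte, 0.00575 for reactive astrocyte, 0.0084 for cholesterol, 0.00948 for matrix and 0.0342 for fibroblast transcripts. None of these 11 calls held with an estimated correlation. Camera gave adjusted p = 0.221 with an estimated correlation for the ATF4, astrocyte, glycolysis, neural stem, ERK and reactive astrocyte lists, 0.274 for hypoxia, 0.392 for oligodendrocyte and 0.473 for cholesterol, matrix and fibroblast lists. The fibroblast call was also lost with a filter of 5 CPM in 2 libraries (camera adjusted p = 0.0552). YAP/TAZ targets (6 higher, 14 lower of 21) had a camera adjusted p of 0.0811; it was 0.0241 without HER2CA day 15 replicate B and 0.0461 without control replicate B. The lists of DNA replication (13 higher, 7 lower of 26, camera adjusted p = 0.261), mitosis (3 and 13 of 28, 0.42), neuron (4 and 9 of 18, 0.279), microglia (1 and 12 of 20, 0.263) and endothelial transcripts (0 and 1 of 5, 0.559) did not pass. Nor did ependymal (3 and 6 of 15, 0.293), actin (8 and 18 of 29, 0.0976), p53 (4 and 13 of 22, 0.104), interferon (7 and 10 of 25, 0.762) and inflammatory transcripts (8 and 6 of 19, 0.7). The interferon median was −0.40 although its camera direction was up. With members at 0 counts set to their bound, the median was −1.38 rather than −1.50 for oligodendrocyte, −0.48 rather than −0.62 for neuronal and −0.61 rather than −0.93 for reactive astrocyte transcripts. Adjusted over the list alone, lower members numbered 12 for mitosis, 8 for neuron, 11 for microglia and 22 for matrix, and higher members 1 for ependymal transcripts.

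Of all genes, 10308 differed (edgeR quasi-likelihood), 5082 higher and 5226 lower in HER2CA day 15, with 1381 and 2652 at least 2-fold. With no scaling factors the split was 2304 higher and 3586 lower, and upper-quartile factors shifted the median log2 fold change of all genes from −0.02 to −0.17. Yap1 was lower (log2 fold change −0.46, SE 0.0679, edgeR quasi-likelihood adjusted p = 1.78e-05, but −0.51 and adjusted p = 0.144 with no scaling factors). Wwtr1 was higher by 0.23 (SE 0.0681, edgeR quasi-likelihood adjusted p = 0.00631), a call lost without control replicate B (0.0523), without HER2CA day 15 replicate B (0.0788), with upper-quartile factors (0.331) and with no scaling factors (0.648). The largest increases were Ostn (1375 counts against 1, ratio 1362, 95% interval 244 to 53825), Cyp4b1 (9.06, SE 0.281), Fibin (8.37, SE 0.474), the growth factor gene Bmp3 (6.77, SE 0.199), Kcnt2 (316 counts against 3, ratio 104, 35.4 to 509) and Thsd4 (6.57, SE 0.184). The largest decreases were Miat (3 counts against 453, ratio of controls 152, 51.8 to 742), Angpt2 (−6.41, SE 0.208), the acetylcholine receptor gene Chrna4 (3 counts against 256, ratio of controls 86.2, 29.2 to 421), Padi2 (−6.18, SE 0.146), S100b (−5.50, SE 0.262) and Ndrg2. Genes changed in this comparison and in that of the 2 day 15 groups mostly had opposite signs, 8393 of 8859 (correlation across genes −0.78, −0.502 with simulated unchanged groups; covariance −1.37, simulated −0.012, difference −1.35). The HER2CA day 15 libraries enter both comparisons with opposite signs. Spread between libraries accounts for little of this excess, since the simulated groups gave a covariance of −0.012 and at most 2 genes called in both. A deviation common to both HER2CA day 15 libraries was not simulated and may still add to it. Independent lists would share 2017 genes higher here and lower there and 2130 the other way, against 4234 and 4159 observed.

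Gliomaspheres were profiled as the fully transformed state. Against controls, all 28 mitotic transcripts and all 26 DNA replication transcripts were higher, among them cyclin A2, Ccna2 (1.11 ± 0.282 to 102 ± 9.48 CPM; SD, n = 2 in each group), Cenpf (log2 fold change 5.43, SE 0.138), the helicase subunit Mcm5 (5.23, SE 0.15) and Rrm2 (3.03, SE 0.0973). Oligodendrocyte-lineage transcripts were higher in 14 of 18 cases, among them the transcription factors Olig1 (3.82, SE 0.122) and Olig2 (2.41, SE 0.0871), neuronal transcripts in 13 of 18, and ERK outputs in 14 of 19, among them Dusp6 (28.2 ± 1.07 to 161 ± 15 CPM) and Spry1 (5.3 ± 0.375 to 47.3 ± 4.36 CPM). Actin and adhesion transcripts were lower in 21 of 29 cases, among them Acta2 (−3.34, SE 0.12) and Tagln (−3.03, SE 0.108), p53 targets in 16 of 22, among them the cell cycle inhibitor Cdkn1a (−1.48, SE 0.085) and Phlda3 (−1.20, SE 0.07), and matrix transcripts in 20 of 30, among them Col6a1 (−1.76, SE 0.087) and Col12a1 (−1.92, SE 0.0954). With an estimated correlation the mitosis call held (camera adjusted p = 0.0314) and the other calls were lost (0.104 for DNA replication and ERK, 0.142 for oligodendrocyte, 0.158 for neuron, actin and p53, 0.227 for matrix).

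Astrocyte transcripts were higher in 17 of 26 cases, among them Slc6a11 (3.86, SE 0.133) and S100b (3.05, SE 0.119), neural stem in 14 of 23 and cholesterol synthesis in 19 of 23. YAP/TAZ targets were lower in 13 of 21 cases and higher in 5, hypoxia lower in 15 of 19, glycolysis in 11 of 16, ependymal in 12 of 15, fibroblast in 9 of 14 and microglia in 10 of 20 cases. Of 25 reactive astrocyte transcripts 10 were higher and 12 lower. Mitosis kept its call with an estimated correlation (camera adjusted p = 3.69e-74, and 0.0314 with it). The others had camera adjusted p of 1.48e-23 for DNA replication, 3.15e-09 for actin, 5.78e-09 for oligodendrocyte, 5.41e-08 for ERK and 3.73e-07 for astrocyte lists. It was 0.00011 for p53, 0.000144 for matrix, 0.000168 for neuron and 0.000285 for neural stem lists. It was 0.000308 for hypoxia, 0.000436 for cholesterol, 0.000579 for ependymal and 0.00134 for fibroblast lists, and 0.0032 for YAP/TAZ, 0.00645 for glycolysis, 0.00975 for microglia and 0.0192 for reactive astrocyte lists. These calls were lost. Camera gave adjusted p = 0.104 with an estimated correlation for DNA replication, ERK, neural stem and ependymal, 0.142 for oligodendrocyte and 0.158 for actin, neuron and p53 lists. It gave 0.227 for astrocyte, fibroblast, matrix, cholesterol and reactive astrocyte, 0.295 for YAP/TAZ and hypoxia, 0.385 for microglia and 0.392 for glycolysis. The reactive astrocyte call was also lost with no scaling factors (camera adjusted p = 0.13). The endothelial (1 higher, 1 lower of 5, camera adjusted p = 0.656), ATF4 (11 and 7 of 24, 0.928), interferon (4 and 8 of 25, 0.225) and inflammatory lists (4 and 8 of 19, 0.418) did not pass. The inflammatory mean was 0.24 and its median −0.27; the ATF4 mean was −0.06 and its median 0.02, or 0.14 with Fgf21 at its bound and −0.02 with upper-quartile factors. Adjusted over the list alone, 15 ERK and 2 fibroblast transcripts were higher, and 3 astrocyte and 13 ependymal transcripts lower.

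In all, 8780 genes differed (edgeR quasi-likelihood), 4427 higher and 4353 lower in gliomaspheres, with 1550 and 1167 at least 2-fold. With no scaling factors, which leave the Rn45s share of gliomaspheres B uncorrected, the median of all genes moved from −0.01 to −0.33 and the split to 1386 and 3260. Removing Rn45s and Lars2, an alternative added after seeing the data, gave 4283 higher and 4528 lower. Yap1 (133 ± 4.09 CPM, log2 fold change −0.07, SE 0.0685, edgeR quasi-likelihood adjusted p = 0.358) and Wwtr1 (0.04, SE 0.0689, 0.604) did not pass, and Erbb2 was lower (−0.51, SE 0.0927, edgeR quasi-likelihood adjusted p = 0.000193). The largest increases were the neurofilament gene Nefl (7.92, SE 0.285), St6gal2 (182 counts against 1, ratio 271, 95% interval 48.1 to 10777), Serpinb11 (450 against 3, ratio 224, 76.05 to 1089), the glutamate receptor gene Grm5 (7.62, SE 0.166), Tk1 (7.17, SE 0.321) and E2f8 (7.12, SE 0.294). The largest decreases were Cnn1 (−5.15, SE 0.233), Ogn (−4.70, SE 0.335), Piwil2 (−4.40, SE 0.411), Plin4 (−4.37, SE 0.138), Nov (−4.36, SE 0.231) and Cyb561 (−4.08, SE 0.259).

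Against HER2CA day 15, gliomaspheres again had higher transcripts of mitosis (28 of 28, among them Top2a, 6.09 ± 0.326 to 224 ± 1.73 CPM, and Cenpf, log2 fold change 6.23, SE 0.15) and DNA replication (23 of 26, among them Rrm2, 4.00, SE 0.106, and Uhrf1, 3.54, SE 0.104). Astrocyte transcripts were higher in 25 of 26 cases, among them the potassium channel gene Kcnj10 (27.8 ± 3.54 to 638 ± 30.9 CPM; SD, n = 2 in each group) and Ndrg2 (5.43, SE 0.131). ERK outputs were higher in 16 of 19 cases, among them Ccnd1 (3.64, SE 0.0816) and Etv4 (4.38, SE 0.105), and oligodendrocyte-lineage transcripts in 15 of 18, among them Olig1 (6.12, SE 0.138) and Olig2 (3.80, SE 0.0934). All 24 ATF4 stress response transcripts were lower, among them Nupr1 (−6.11, SE 0.109) and Trib3 (−6.73, SE 0.165). Cholesterol synthesis was higher in 22 of 23 cases, among them Dhcr7 (2.67, SE 0.0969), and neural stem transcripts in 20 of 23, among them Lfng (3.40, SE 0.0866). With an estimated correlation the ERK call held (camera adjusted p = 0.047) and the other calls were lost (from 0.128 for neural stem to 0.233 for DNA replication).

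Neuronal (13 of 18), glycolytic (13 of 16) and hypoxia (14 of 19) transcripts were higher too, and actin and adhesion transcripts lower in 16 of 29 cases. The ERK list kept its call with an estimated correlation (camera adjusted p = 4.95e-10, and 0.047 with it). The others had camera adjusted p of 4.49e-34 for mitosis, 1.37e-19 for astrocyte, 3.29e-19 for ATF4, 2.29e-09 for oligodendrocyte and 5.43e-08 for neural stem lists. It was 7.44e-08 for DNA replication, 5.69e-06 for cholesterol, 0.000431 for glycolysis, 0.00079 for neuron, 0.0183 for actin and 0.0223 for hypoxia. These calls were lost. Camera gave adjusted p = 0.135 with an estimated correlation for mitosis, 0.15 for astrocyte and 0.174 for ATF4, oligodendrocyte and cholesterol lists. It gave 0.128 for neural stem, 0.233 for DNA replication, 0.439 for glycolysis, 0.201 for neuron, 0.548 for actin and 0.608 for hypoxia. YAP/TAZ targets (10 higher, 8 lower of 21, camera adjusted p = 0.835), microglia (5 and 5 of 20, 0.56), fibroblast (6 and 5 of 14, 0.888), endothelial (2 and 1 of 5, 0.517) and ependymal lists (2 and 9 of 15, 0.299) did not pass. Nor did matrix (10 and 14 of 30, 0.845), p53 (7 and 12 of 22, 0.376), interferon (6 and 8 of 25, 0.401), reactive astrocyte (13 and 6 of 25, 0.408) and inflammatory lists (8 and 7 of 19, 0.517). Camera's direction was down where the median was above 0 for YAP/TAZ, microglia, interferon and inflammatory lists. The matrix mean was 0.12 and its median −0.08, or 0.04 with upper-quartile factors. Adjusted over the list alone, higher members numbered 24 for DNA replication and 4 for microglia, and lower members 5 for hypoxia and 6 for interferon.

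Of all genes 10727 differed (edgeR quasi-likelihood), 5228 higher and 5499 lower, with 3013 and 1920 at least 2-fold. The median of all genes was −0.03, against 0.08 with upper-quartile factors and −0.30 with no scaling factors. The largest increases were Omg (1411 counts against 0, at least 708-fold), Serpinb11 (450 against 0, at least 226-fold), Lpo (1705 against 1, ratio 2567, 95% interval 460.1 to 101455), Btbd17 (2459 against 2, ratio 1851, 512 to 15294), Lrfn2 (208 against 0, at least 104-fold) and the serotonin receptor gene Htr3a (206 against 0, at least 103-fold). The largest decreases were Nrip2 (0 counts against 365, at least 80.8-fold), Ostn (1 against 1375, ratio of HER2CA day 15 913, 164 to 36097), Thsd4 (−7.69, SE 0.229), Cdsn (−6.75, SE 0.176), Trib3 and Avil (−6.53, SE 0.217). Yap1 was higher (0.39, SE 0.069, edgeR quasi-likelihood adjusted p = 0.000106, but 0.10 and adjusted p = 0.772 with no scaling factors) and Erbb2 lower (−0.44, SE 0.0929, adjusted p = 0.000465 by edgeR quasi-likelihood). Wwtr1 was lower by a log2 fold change of −0.19 (SE 0.0688, edgeR quasi-likelihood adjusted p = 0.021), a call lost without HER2CA day 15 replicate B (0.176), without gliomaspheres replicate B (0.152), with upper-quartile factors (0.341), with no scaling factors (0.167), with the 5 CPM filter (0.0753) and with only the libraries of these 2 groups (0.109).

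The libraries labelled 4OH-TAM were also set against controls. Interferon-response transcripts were higher in 24 of 25 cases (camera adjusted p = 4.47e-23, and 0.0327 with an estimated correlation), and the guanylate-binding and GTPase genes Gbp4 (log2 fold change 6.35, SE 0.301) and Iigp1 (0.159 ± 0.0079 to 13.4 ± 0.0432 CPM; SD, n = 2 in each group) were among the largest increases, with Steap4 (288 counts against 2, ratio 139, 95% interval 38.04 to 1151). Gbp4 shares exons with Gbp8 and Gbp9 in the annotation, so its counts are uncertain. ATF4 stress transcripts were higher in 23 of 24 cases, microglia and macrophage in 17 of 20, oligodendrocyte-lineage in 16 of 18, inflammatory in 16 of 19 and mitotic transcripts in 20 of 28. Glycolytic transcripts were lower in 15 of 16 cases, hypoxia in 17 of 19, p53 targets in 19 of 22, cholesterol synthesis in 17 of 23 and actin in 14 of 29. All list calls but that of interferon were lost with an estimated correlation (camera adjusted p from 0.0681 to 0.413). The largest decreases were Ddn (−3.01, SE 0.271), Mreg (−2.93, SE 0.206) and the Nogo receptor gene Rtn4r (−2.82, SE 0.17).

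ERK outputs were higher in 12 of 19 cases, astrocyte transcripts in 14 of 26, neuronal in 11 of 18, fibroblast in 11 of 14, endothelial in 3 of 5, ependymal in 12 of 15, matrix in 15 of 30 and reactive astrocyte transcripts in 16 of 25. Camera adjusted p was 6.85e-38 for ATF4, 6.68e-19 for microglia, 6.84e-12 for oligodendrocyte, 2.44e-12 for hypoxia, 8.29e-11 for glycolysis, 4.29e-10 for cholesterol and 4.5e-08 for inflammatory lists. It was 9.01e-08 for p53, 2.59e-05 for mitosis, 0.000196 for ependymal, and 0.000416 for fibroblast and reactive astrocyte lists. It was 0.000927 for neuron, 0.00114 for ERK, 0.00242 for astrocyte, 0.00569 for endothelial, 0.00583 for actin and 0.0172 for matrix lists. These calls were lost. Camera gave adjusted p = 0.0681 with an estimated correlation for ATF4, microglia, oligodendrocyte, inflammatory and ependymal lists. It gave 0.0825 for hypoxia, glycolysis, cholesterol, endothelial, neuron and reactive astrocyte lists, 0.0797 for p53, 0.188 for mitosis, 0.151 for fibroblast and ERK, 0.382 for astrocyte, 0.326 for actin and 0.413 for matrix. The matrix call was also lost without 4OH-TAM replicate A (camera adjusted p = 0.0622), without control replicate B (0.0507) and with no scaling factors (0.0815). YAP/TAZ targets (10 higher, 7 lower of 21, camera adjusted p = 0.727), DNA replication (10 and 3 of 26, 0.395) and neural stem transcripts (10 and 9 of 23, 0.456) did not pass. Adjusted over the list alone, 6 actin transcripts were higher, and 1 ATF4 and 1 interferon transcript lower.

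Of all genes 8061 differed (edgeR quasi-likelihood), 4221 higher and 3840 lower, with 1648 and 402 at least 2-fold. With no scaling factors the split was 2115 and 539. Yap1 (−0.42, SE 0.0678, edgeR quasi-likelihood adjusted p = 9.77e-05) and Wwtr1 (−0.50, SE 0.0687, adjusted p = 2.22e-05 by the same test) were lower than in controls. Both calls were lost with no scaling factors (Yap1 −0.35, edgeR quasi-likelihood adjusted p = 0.505, and Wwtr1 −0.43, 0.372). Erbb2 had a log2 fold change of −0.18 (SE 0.0862, edgeR quasi-likelihood adjusted p = 0.0813, or 0.044 with only the libraries of these 2 groups).

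The 200 most significant genes at least 2-fold higher in gliomaspheres than in controls were then followed in the 2 day 15 groups. Of these, 180 were higher and 9 lower in the libraries labelled 4OH-TAM than in HER2CA day 15 (median log2 fold change 2.25, camera adjusted p = 7.58e-40, and adjusted p = 0.0529 with an estimated correlation). Of all 13607 genes, 5547 were higher and 5400 lower. This set was not followed in the libraries labelled 4OH-TAM against controls. The counts therefore do not separate a rise in those libraries from a fall in HER2CA day 15. Of the 200 lower in gliomaspheres, 97 were higher and 71 lower (median 0.17, camera adjusted p = 0.314). Without 4OH-TAM replicate B that median was 0.27 (camera adjusted p = 0.0228), and without gliomaspheres replicate A it was 0.064. Of 7173 genes changed in both comparisons, which share no library, 4253 had the same sign (59.3%, correlation across genes 0.308, genes not being independent replicates). Independent lists would share 1805 genes higher and 1728 lower in both, against 2325 and 1928 observed. Genes changed in HER2CA day 15 and in gliomaspheres, each against controls, had the same sign in 3756 of 6830 cases (correlation across genes 0.0288, 0.461 with simulated unchanged groups that share the controls; covariance 0.0396, simulated 0.012, difference 0.0275). By the same reckoning, 1653 genes would be higher and 1672 lower in both, against 1724 and 2032 observed. Part of the excess may come from the shared controls. By mean root-mean-square log2 difference between libraries, HER2CA day 15 lay 1.2 from controls, 1.4 from the libraries labelled 4OH-TAM and 1.6 from gliomaspheres, while the libraries labelled 4OH-TAM lay 0.881 from controls and 1.0 from gliomaspheres. Replicates of a group lay 0.203 to 0.371 apart.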

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

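The removal of Rn45s and Lars2 and the use of no scaling factors were chosen after seeing the data; the other settings were planned. Tested against a 1.5-fold change, 6071 genes differed between the 2 day 15 groups (2339 lower), 5456 between HER2CA day 15 and controls (2302 higher, 3154 lower), 3393 between gliomaspheres and controls (1897, 1496), 6237 between gliomaspheres and HER2CA day 15 (3431, 2806) and 2417 between the libraries labelled 4OH-TAM and controls (1804, 613), since that test asks for a larger change. With no scaling factors the counts were 6375 (2037 lower), 5890 (2304 higher), 4646 (1386 higher), 3030 higher in gliomaspheres than in HER2CA day 15, and 2654 (2115, 539). That setting leaves gliomaspheres B uncorrected (TMM factor 0.637, against 1.057 in gliomaspheres A), and all 8 libraries share one estimate of the spread. Between HER2CA day 15 and controls the median of all genes moved only from −0.02 to −0.07. A call lost under that setting therefore need not mean a smaller change, also where no gliomaspheres are compared. Whether this accounts for all of the lower counts was not tested. Called lists numbered 0, 0, 1, 1 and 1 in the 5 comparisons with an estimated correlation. That setting also tests on only 4 residual degrees of freedom, so these losses need not reflect correlation alone. With fry, which does not compare a list with other genes, 20 lists were called for HER2CA day 15 against controls. The set higher in gliomaspheres had median 2.25 and adjusted p = 0.0529 with an estimated correlation; the lower set had 0.17 and 0.00886 with fry, and medians from 0.064 (without gliomaspheres replicate A) to 0.27 (without 4OH-TAM replicate B) with 1 library left out; the cause was not tested. Replicate letters did not pair the libraries (deviations between groups correlated at −0.0299 to 0.051). With the replicate block 10948, 10300, 8761, 10704 and 8072 genes were called. There, 110 of 110 list outcomes and 146 of 146 named-gene outcomes were unchanged, counting those called and those not called. With 1 library left out, 1163 of 1168 named-gene outcomes and 874 of 880 list outcomes were unchanged, called or not. The lone library was assumed to vary like the other groups. Some of these fits left out a library of neither compared group. Most named genes were also picked for large or significant changes in these data, so little change was open to them. Upper-quartile factors kept 142 of 146 named-gene outcomes. Yap1 between the 2 day 15 groups (0.25, adjusted p = 0.00352, edgeR quasi-likelihood) and Erbb2 between HER2CA day 15 and controls (−0.23, 0.0256) passed, and 2 Wwtr1 calls were lost. The 1.5-fold test ended 11 calls among the 146 outcomes. No scaling factors ended 10 calls among the 146 outcomes, one being Wwtr1 between the 2 day 15 groups (−0.61, edgeR quasi-likelihood adjusted p = 0.0738). DESeq2, relative log expression factors and the removal of Rn45s and Lars2 changed no named-gene call. Running without the low-count filter removed no gene and tests nothing. No call of a named gene or list changed direction. The majority direction of changed genes did turn. Between the 2 day 15 groups it went from higher to lower with a filter of 5 CPM in 2 libraries (4738 higher, 4770 lower). In gliomaspheres against controls it went from higher to lower with upper-quartile factors (4132 higher, 4709 lower), with Rn45s and Lars2 removed (4283, 4528) and with no scaling factors. Against HER2CA day 15 it went from lower to higher with upper-quartile factors (5730, 4826), the 1.5-fold test, only the libraries of these groups (5199, 5019) and without gliomaspheres replicate B (5334, 5142). Depth limits the lowest genes: at 0 to 3 counts in a group, only bounds or count ratios were given.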

Other observations

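The 6 gene families and all tests of explanations in this part were chosen after the results were seen, and the rule for microglia was made stricter after its first outcome. The first, looser rule had favoured a larger share of microglia. The stricter rule, which also asks for higher Cx3cr1 and Csf1r, leaves it open. Each family was tested in all 5 comparisons, with camera p adjusted over the 6 families, and is given below for each comparison in which that p was below 0.05, and for the synthetases in gliomaspheres against controls.

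Of 20 cytosolic aminoacyl-tRNA synthetase genes, whose enzymes charge tRNAs, 19 were higher and 1 lower in HER2CA day 15 than in controls (median log2 fold change 2.05, camera adjusted p = 1.9e-16, adjusted p = 0.244 with an estimated correlation). Wars was at 566 CPM against 75.5 CPM and Gars at 475 CPM against 89.9 CPM. In the libraries labelled 4OH-TAM 14 were higher and 3 lower than in controls (median 0.86, camera adjusted p = 4.36e-06, adjusted p = 0.257 with an estimated correlation), and 0 higher and 19 lower than in HER2CA day 15 (median −1.03, camera adjusted p = 9.87e-08, adjusted p = 0.17 with an estimated correlation). In gliomaspheres 5 were higher and 4 lower than in controls (median −0.01, camera adjusted p = 0.917), and 0 and 18 than in HER2CA day 15 (median −2.03, camera adjusted p = 4.03e-12, adjusted p = 0.211 with an estimated correlation). Of 74 cytosolic ribosomal protein genes, 61 were higher and 1 lower in HER2CA day 15 than in controls (median 0.62, camera adjusted p = 3.23e-05, adjusted p = 0.59 with an estimated correlation), but 29 and 0 with no scaling factors. Compared with HER2CA day 15, 1 was higher and 65 lower in the libraries labelled 4OH-TAM (median −0.75, camera adjusted p = 3.87e-07, adjusted p = 0.441 with an estimated correlation; 0 and 32 with no scaling factors). In gliomaspheres 5 were higher and 49 lower than in HER2CA day 15 (median −0.40, camera adjusted p = 0.0113, adjusted p = 0.869 with an estimated correlation; 0 and 36 with no scaling factors).

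Of 37 proteasome subunit genes, 1 was higher and 28 lower in the libraries labelled 4OH-TAM than in controls (median −0.44, camera adjusted p = 5.88e-06, adjusted p = 0.137 with an estimated correlation). With no scaling factors 0 passed singly, although the family kept its call (median −0.37, camera adjusted p = 0.000969). In HER2CA day 15, 27 were higher and 4 lower than in controls (median 0.39, camera adjusted p = 0.00503, adjusted p = 0.311 with an estimated correlation), against 22 and 8 with upper-quartile factors and 8 and 4 with no scaling factors. Between the 2 day 15 groups, 3 were higher and 33 lower in the libraries labelled 4OH-TAM (median −0.84, camera adjusted p = 9.87e-08, adjusted p = 0.0944 with an estimated correlation), and 3 and 24 with no scaling factors. In gliomaspheres 1 was higher and 25 lower than in controls (median −0.31, camera adjusted p = 0.0228, adjusted p = 0.624 with an estimated correlation). That call was lost with no scaling factors (median −0.625, camera adjusted p = 0.0763), where the median of all genes was −0.33. Compared with HER2CA day 15, 4 were higher and 32 lower in gliomaspheres (median −0.67, camera adjusted p = 4.12e-05, adjusted p = 0.211 with an estimated correlation). Of 35 respiratory complex I genes, 2 were higher and 23 lower in the libraries labelled 4OH-TAM than in HER2CA day 15 (median −0.36, camera adjusted p = 0.026, adjusted p = 0.523 with an estimated correlation), against 7 and 14 (median −0.15) with upper-quartile factors and 1 and 3 with no scaling factors. Compared with controls 0 were higher and 15 lower there (median −0.22, camera adjusted p = 0.0295, adjusted p = 0.624 with an estimated correlation), and 0 passed singly with no scaling factors. The medians with camera adjusted p below 0.05 kept their sign under the 4 scalings tried.

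All 11 complement genes were higher in the libraries labelled 4OH-TAM than in controls (median 2.48, camera adjusted p = 3.6e-18, and 0.0262 with an estimated correlation), and than in HER2CA day 15 (median 3.31, camera adjusted p = 9.43e-09, adjusted p = 0.0944 with an estimated correlation). Of 11 genes of MHC class I and antigen processing, 7 were higher and 2 lower than in controls (median 0.47, camera adjusted p = 0.022, adjusted p = 0.257 with an estimated correlation). With no scaling factors 4 were higher and 0 lower. All 11 were higher than in HER2CA day 15 (camera adjusted p = 0.000524, adjusted p = 0.111 with an estimated correlation). In HER2CA day 15, 1 was higher and 8 lower than in controls (median −0.65, camera adjusted p = 0.034, adjusted p = 0.311 with an estimated correlation). These medians kept their sign under the same scalings. The C1q genes belong both to this complement family and to the microglia list. By their definitions, the proteasome and MHC class I families also share members, and the complement and MHC class I families share members with the reactive astrocyte list. Results for these families and lists are therefore not separate.

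The libraries labelled 4OH-TAM had higher ERK outputs, Ctgf and Cyr61 than HER2CA day 15, and Yap1 was not lower. Scaling of the libraries was examined for the ERK outputs only, whose median was at least 1.38 under 5 scalings. The scalings tried moved the median of all genes only from 0.01 to at most 0.22. They could not have removed a shift of that size, so no conclusion is drawn from this test. Yap1 did depend on scaling (0.25 with upper-quartile factors, edgeR quasi-likelihood adjusted p = 0.00352). An exchange of labels between the 2 day 15 groups may be weighed. The log2 fold change of Wwtr1 (−0.73, or −0.61 and adjusted p = 0.0738 by edgeR quasi-likelihood with no scaling factors) goes with the labels. That of Yap1 (0.04) goes with neither reading. Neither gene moved 2-fold, and counts over a whole gene include exons that Cre leaves in place. The counts of these 2 genes therefore cannot tell the 2 readings apart, and other transcripts were not weighed for this. Deletion of YAP and TAZ would be expected to lower the target list. Its median of 0.69 goes the other way, but camera adjusted p was 0.364 with an estimated correlation, so the list does not decide whether the alleles were deleted. Reads over the floxed exons would show which libraries lost the alleles.

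Microglia and macrophage transcripts were higher in the libraries labelled 4OH-TAM than in controls, 17 of 20 (85%) with 0 lower. A larger share of microglia in those cultures is a candidate explanation: Lyz2 was at 721 CPM against 61.5, Ctss at 67.2 against 18.4, C1qb at 64.5 against 10.9 and Tyrobp at 24.9 against 4.36, and all 20 genes were also detected in controls. More cells of unchanged state would raise all their transcripts. Among the higher ones were P2ry12 (1.86 against 0.519 CPM), Tmem119 (1.17 against 0.302) and Csf1r (21.2 against 8.71). The members that did not pass were Cx3cr1, at 5.66 against 5.94 CPM (log2 fold change −0.07, SE 0.151, edgeR quasi-likelihood adjusted p = 0.713), Cd68, at 88.8 against 88.5, and Ly86, at 1.28 against 0.884. A larger share and a changed state therefore cannot be told apart. A smaller share of astrocytes cannot be excluded either: the astrocyte median was 0.31 (camera adjusted p = 0.00242, adjusted p = 0.382 with an estimated correlation), and oligodendrocyte, neuronal, endothelial, ependymal and fibroblast lists were higher as well. A response to 4OH-TAM or to the deletion was not tested.

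ATF4 stress response transcripts were higher than in controls in both day 15 groups, which received doxycycline. Doxycycline in the medium as the whole cause is argued against by gliomaspheres, kept in the same medium: their median against controls was 0.0246 (−0.02 with upper-quartile factors), 24 of 24 members were lower than in HER2CA day 15 and 23 of 24 lower than in the libraries labelled 4OH-TAM. Gliomaspheres also differ in duration and in growth as suspension, so a transient or culture-dependent effect of doxycycline may remain. Gliomaspheres are HER2CA cells too, so the same values do not separate doxycycline from expression of the oncogene, and whether controls were transduced is not given. No biological explanation is therefore singled out.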
